A study of Homo sapiens with 10 samples.

How the data were processed

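CUT&RUN maps where a histone modification sits by tethering a nuclease to an antibody on intact chromatin and sequencing the released DNA. The series profiled S2-VP10, an established human pancreatic adenocarcinoma cell line, as 4 libraries from cells grown in flat culture (IgG, H3K4me1, H3K4me3 and H3K27ac) and 6 libraries from cells sorted out of S2-VP10 xenografts. The xenograft libraries comprise 3 (IgG, H3K4me1 and H3K27ac) from each of the ROR1-high and ROR1-low populations. Each combination of cell source and antibody is 1 library, so none has a replicate. Per the labels' protocols, chromatin was cleaved with a commercial CUT&RUN kit under a modified protocol and libraries were made with an NEBNext Ultra kit.

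The peak lists of cultured H3K4me1 and cultured H3K27ac, and 1 list of H3K4me1 peaks overlapping H3K27ac, were analysed. The other 8 libraries were not analysed here, so neither the ROR1-high against ROR1-low comparison nor the IgG background is reported. Per the submitters' processing notes, the tools were Bowtie2 2.3.4.1 and deepTools 3.5.1, with MACS2 and bedtools also named for the libraries with peak lists. Those notes also name the human build hg19 and the yeast build sacCer3; the role of the yeast build is not given in the sources used here. Alignment options, the control library of the peak calls, their parameters and any read filters are also not given in the sources used here. Peaks were listed separately for each library, with no pooling of libraries visible in the lists.

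Each deposited peak carries a fold enrichment, a linear ratio over the background the authors' peak caller estimated. Each deposited peak also carries a −log10 p-value and a −log10 q-value against that background, and the largest q-value was 0.0482 for H3K4me1 and 0.0476 for H3K27ac. The deposited score equalled the integer part of the −log10 q-value multiplied by 10 for 99.9% of H3K4me1 peaks and 100% of H3K27ac peaks. The deposited summit offset gives the position of the highest signal inside a peak. These values are the authors' own for each peak and were used only to describe, rank or filter peaks within a list. The lists hold no read counts, so sequencing depth is unknown, and a longer list can come from a deeper library or from a stronger antibody as well as from wider marking of the chromatin.

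All coordinates are hg19. The furthest H3K4me1 peak on chromosome 1 ends at 249200202, inside the hg19 length of 249250621 but beyond the last annotated gene of chromosome 1 in GRCh38.p14, which ends at 248937099. The gene table used here is that of GRCh38.p14, so no peak was assigned to a gene, promoter or intron, and the planned analyses of 17 gene lists with 264 members, of promoter location and of the ROR1 gene itself were not run. Regions were described instead by hg19 cytogenetic bands, taken from circlize 0.4.16 with chromosome lengths checked in GenomeInfoDb 1.38.1. The gene table served only for the number of protein-coding genes per chromosome. The rule for named genes, written before the data were examined, took ROR1, up to 4 members of each list ranked by nearby H3K27ac and the genes at the 20 largest H3K27ac clusters. Without a gene assignment this became the bands that hold ROR1 and pancreatic cancer driver genes of the fixed list, from textbook band positions; some members of that list are not reported here. The bands of MYC and GATA6 were added after their values were seen.

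Overlap was counted as 1 bp or more shared. Expected overlap came from 1000 random placements in which the peaks of each chromosome were shifted together around its span, which keeps widths and spacing, and the two-sided permutation p doubles the smaller of the shares of placements at or beyond the observed value on either side. The smallest two-sided p these placements give is 0.002, and it tests position along the genome within these libraries, not a difference between conditions. Shares carry Wilson 95% intervals, which cover counting error only and treat neighbouring peaks as independent. Shares by chromosome, and their ratios to an expected share, carry 95% intervals from 2000 bootstrap draws of 5 Mb blocks. Shares and densities by band stain carry 95% intervals from 2000 bootstrap draws of whole bands of that stain. Densities by chromosome carry no interval. Deciles of fold enrichment were compared with 200 placements. A standardised share divides the observed share of a chromosome by the share expected from the H3K4me1 fold deciles of its peaks. Peaks per Mb were related to gene density over 23 chromosomes with 10000 permutations, and the 6 correlation tests were adjusted together by the Benjamini-Hochberg method. They were repeated without chromosomes 17 and 19, the farthest from the median gene density. Peaks per chromosome were fixed as a description beforehand. The analyses by decile, flank, gene density, stain, band and run, and the share with H3K27ac by chromosome, were added after the lists were seen. H3K27ac peaks were joined into clusters across gaps of up to 12 kb and ranked by covered bases. A run was a series of consecutive H3K27ac peaks without H3K4me1 and with no gap over 100 kb. Bands of at least 1 Mb outside centromeres, stalks and variable regions were ranked by peaks per Mb, and their percentile gives their rank among all ranked bands on a scale to 100.

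Alternatives fixed before the data were examined were an overlap of at least 50% of the shorter peak, peaks extended by 500 bp, the higher-scoring 50% of each list, peaks merged across 1 kb, placement within 1 Mb windows, autosomes alone, and cluster joins of 5 and 20 kb. The overlap count was tested on simulated lists in which 20, 50 and 90% of H3K27ac peaks were placed on H3K4me1 peaks. With chance overlap added, the expected shares were 22.4, 51.5 and 90.3%, and the recovered shares were 22.3, 51.8 and 89.8%. Of 40 unrelated list pairs with 199 placements each, 3 gave a p under 0.05. Both lists of each pair were placed at uniform random positions along each chromosome. They lack the clustering of the real peaks, so this does not test the p for clustered lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.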

Results

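Histone H3 monomethylated at lysine 4 (H3K4me1), which marks enhancers, and H3 acetylated at lysine 27 (H3K27ac), which marks active enhancers and promoters, were mapped by CUT&RUN in cultured S2-VP10 pancreatic adenocarcinoma cells. The series holds 10 libraries, of which the cultured H3K4me1 and H3K27ac libraries are reported here as peak lists. Each mark was measured in 1 library, so no value has a spread between replicates, and no difference between the marks could be set against one. Read depth is unknown because the lists hold no counts.

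H3K4me1 formed a large set of modest peaks across the S2-VP10 genome. The H3K4me1 list held 60717 peaks covering 54.0 Mb, or 1.78% of chromosomes 1 to 22 and X. The median H3K4me1 peak was 613 bp wide (quartiles 378 and 1094 bp) with a fold enrichment of 6.09 (quartiles 4.87 and 8.20). H3K27ac was listed at far fewer sites, with 11206 peaks covering 5.77 Mb, or 0.190% of the same chromosomes. The median H3K27ac peak was 339 bp wide (quartiles 230 and 594 bp) with a fold enrichment of 5.35 (quartiles 4.70 and 6.38). H3K4me1 peaks thus outnumbered H3K27ac peaks by 5.42 to 1 and covered 9.37 times as many bases. The widest peaks reached 17860 bp for H3K4me1 and 8960 bp for H3K27ac, and 7.05% and 3.90% of the peaks lay at the smallest width of their list, 275 and 170 bp. These ratios describe list sizes, which depend on depth and antibody as well as on the chromatin.

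Enhancers in use are commonly recognised by carrying both marks, and the overlap between the lists addresses how far H3K4me1 sites of S2-VP10 cells were also acetylated. Nearly all H3K27ac lay on H3K4me1-marked chromatin: 10223 of 11206 H3K27ac peaks overlapped an H3K4me1 peak, or 91.2% (Wilson 95% interval 90.7 to 91.7). The reverse held for few sites, since 6887 of 60717 H3K4me1 peaks overlapped an H3K27ac peak, or 11.3% (11.1 to 11.6). The remaining 53830 H3K4me1 peaks carried no listed H3K27ac, and 983 H3K27ac peaks carried no listed H3K4me1. By base, 5.23 Mb carried both marks, which was 90.7% of the H3K27ac-covered and 9.68% of the H3K4me1-covered sequence. Random placement gave a mean of 2.95% for H3K27ac peaks (range 2.21 to 4.22) and 0.472% for H3K4me1 peaks (range 0.369 to 0.652). The observed overlaps were 30.9 and 24.0 times these means, each with a two-sided permutation p of 0.002, the smallest that 1000 placements can give. Placement within 1 Mb windows, which keeps regional density, raised the means to 6.78% and 1.05%. It lowered the ratios to 13.5 and 10.8, with the same p. Both kinds of placement can put peaks in sequence where neither list has one. They therefore do not show how far other lists from the same cells, such as one from IgG, would overlap. Without the strongest 10% of H3K4me1 peaks, a set removed after the data were seen, the share of H3K4me1 peaks with H3K27ac fell to 7.46%.

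The authors' deposited overlap list holds 6887 H3K4me1 peaks, each identical in position and values to a peak of the H3K4me1 list. The recomputed set of H3K4me1 peaks sharing 1 bp or more with H3K27ac also numbered 6887, and 6887 peaks were in both, with 0 in either list alone. Requiring 50% of the shorter peak to be shared left 6675.

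H3K4me1 peaks that also carried H3K27ac were wider and more enriched than those that did not. Their median width was 1633 bp (quartiles 972.5 and 2586.5), against 561 bp (362 and 942) for H3K4me1 peaks without H3K27ac, a ratio of 2.91. Their median fold enrichment was 10.1 (7.42 and 13.0) against 5.74 (4.66 and 7.48), a ratio of 1.76. The probability that an H3K4me1 peak with H3K27ac was wider than one without was 0.828, and that it was more enriched 0.812. Although they were 11.3% of the list by number, these peaks held 13.5 Mb, or 24.96% of all H3K4me1-covered sequence. Among H3K27ac peaks the classes stood closer together. H3K27ac peaks on H3K4me1 had a median width of 352 bp against 253 bp off it, and a median fold enrichment of 5.39 against 5.02. Peaks of 1 library are not replicates, so these contrasts carry no p.

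The share of H3K4me1 peaks with H3K27ac climbed steeply along the range of H3K4me1 enrichment. In the weakest decile 110 of 6072 peaks carried H3K27ac, or 1.81% (1.51 to 2.18). The share was 4.64% in the fifth decile, 14.5% in the eighth and 22.5% in the ninth. In the strongest decile, with fold enrichment from 10.98 to 27.1, it reached 46.3% (45.1 to 47.6), while placement gave 0.349% in the weakest and 0.790% in the strongest decile. Ranking by width gave 1.45% in the narrowest and 50.4% in the widest decile. H3K27ac peaks met H3K4me1 at every strength, from 86.3% in their second decile to 96.4% in the strongest.

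**Figure D1:**
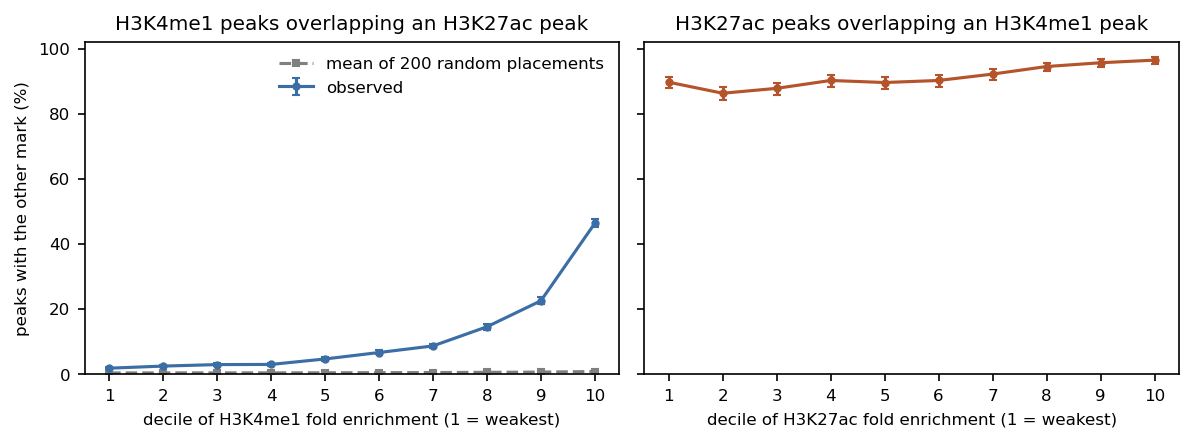
Percentage of peaks overlapping the other mark (vertical axis) in each decile of the authors' fold enrichment (horizontal axis, 1 is the weakest) for H3K4me1 peaks, left, and H3K27ac peaks, right. Points are observed shares and bars are Wilson 95% intervals. The dashed grey line, drawn for H3K4me1 peaks only, is the mean of 200 random placements. The H3K4me1 share climbs from 1.81% to 46.3%, and the H3K27ac share stays between 86.3% and 96.4%.

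Within shared sites, H3K27ac tended to sit centrally on H3K4me1. Of the 11206 H3K27ac summits, 9803 (87.5%) fell inside an H3K4me1 peak, and 43.6% of those lay in the middle 33.3% of its width. The median distance from an H3K27ac summit to the H3K4me1 summit of the same peak was 345 bp, against 500.2 bp for a random point in the same peaks. Most shared H3K4me1 peaks, 4657 (67.6%), held 1 H3K27ac peak, 1483 held 2 and 747 held 3 or more, up to 11.

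The 983 H3K27ac peaks without H3K4me1 were for the most part close to it. Their median distance to the nearest H3K4me1 peak was 513 bp, against 50748 bp after random placement. An H3K4me1 peak lay within 2 kb on at least 1 side of 85.6% of them, against 5.38% by placement. H3K4me1 peaks flanked 441 of the 983 on both sides within 2 kb, or 44.9% (41.8 to 48.0), and no circular shift exceeded 0.974% and no placement within 1 Mb windows exceeded 1.74%.

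Both marks were densest on chromosomes 17, 12, 10 and 11. Chromosome 17 carried 33.9 H3K4me1 and 6.33 H3K27ac peaks per Mb, chromosome 12 carried 26.4 and 6.30, chromosome 10 carried 25.5 and 6.23, and chromosome 11 carried 26.1 and 5.56. Chromosome X was the sparsest, with 9.06 H3K4me1 and 0.921 H3K27ac peaks per Mb. Chromosome 19, which has the most protein-coding genes per Mb (24.5, against a median of 5.64 over chromosomes), carried 16.4 H3K4me1 peaks per Mb and 83 H3K27ac peaks in all, 1.40 per Mb. The share of H3K4me1 peaks with H3K27ac had an interval above the genome-wide 11.3% on chromosome 10, at 15.6% (12.4 to 18.8), and chromosome 12, at 13.8% (11.6 to 16.0). It had an interval below 11.3% on chromosome 19, at 6.51% (3.84 to 9.59; 63 of 968 peaks), chromosome X, at 6.54% (4.12 to 9.04; 92 of 1407), chromosome 14, at 7.56% (4.93 to 10.1), and chromosome 16, at 9.05% (7.01 to 11.1). At equal H3K4me1 fold, an adjustment chosen after the data were seen, chromosome 19 stood at 1.12 times its expected share (0.709 to 1.59), and the ratio excluded 1 only on chromosomes 5 (0.819), 16 (0.821) and 17 (1.21). These are 23 intervals for the share and 23 for the ratio, of which about 5% miss by chance. Intervals from few blocks, such as 12 on chromosome 19 and 7 on chromosome 21, may be too narrow and miss more often.

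**Figure D2:**
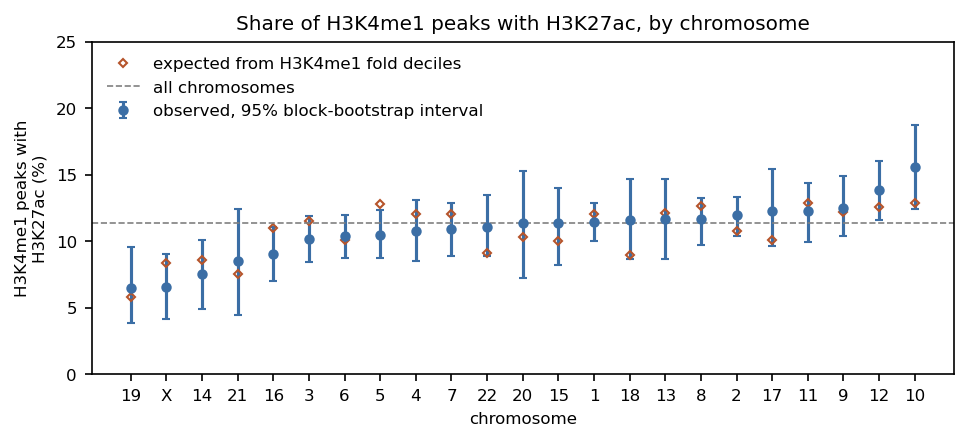
Percentage of H3K4me1 peaks overlapping an H3K27ac peak (vertical axis) on each chromosome (horizontal axis, ordered by share). Blue points and bars are observed shares with 95% block-bootstrap intervals, open diamonds the share expected from the H3K4me1 fold deciles of that chromosome and the dashed line the genome-wide 11.3%; chromosomes 19 and X are lowest at 6.51% and 6.54% and chromosome 10 is highest at 15.6%.

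Gene-rich chromosomes tended to carry more H3K4me1 per Mb by rank. Across the 23 chromosomes, Spearman's rho between protein-coding genes per Mb and H3K4me1 peaks per Mb was 0.60 (permutation p = 0.0035, Benjamini-Hochberg adjusted over 6 tests 0.0210), and Pearson's r was 0.32 (permutation p = 0.143, adjusted 0.236). Without chromosomes 17 and 19, those farthest from the median gene density, r was 0.68 (permutation p = 0.001, adjusted over the same 6 tests 0.0030) and rho was 0.69 (permutation p = 0.0008, adjusted 0.0030). For H3K27ac peaks per Mb, rho was 0.35 (permutation p = 0.103, adjusted 0.236) and r was 0.05 (permutation p = 0.833, adjusted 0.856), and neither passed. Without chromosomes 17 and 19, r was 0.44 (permutation p = 0.0424, adjusted 0.0694) and rho was 0.44 (permutation p = 0.0463, adjusted 0.0694), so the adjusted test was passed in neither set of chromosomes. The share of H3K4me1 peaks with H3K27ac showed no relation that passed the test, with rho −0.04 (permutation p = 0.856, adjusted 0.856) and r −0.30 (permutation p = 0.157, adjusted 0.236), and r was 0.05 (permutation p = 0.843, adjusted 1) without the same chromosomes. Gene counts were taken from GRCh38.p14 and lengths from hg19. Gene and peak densities of a chromosome share its full length as divisor, including bands without any listed peak such as 13p13 and 21p13. A shared divisor can raise a correlation of densities, and the permutations do not account for it.

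Both marks thinned out together from Giemsa-light to Giemsa-dark bands, the latter being gene-poor, late-replicating chromatin. Unstained bands carried 26.7 H3K4me1 peaks per Mb (25.3 to 28.1) and 4.95 H3K27ac peaks per Mb (4.47 to 5.44). The darkest bands carried 10.1 (8.83 to 11.4) and 1.80 (1.39 to 2.23), so the densities fell by factors of 2.64 and 2.76. The share of H3K4me1 peaks with H3K27ac differed less, at 11.5% (10.7 to 12.2) in unstained and 9.93% (8.65 to 11.2) in the darkest bands, with overlapping intervals.

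Among 747 ranked bands, with medians of 20.7 H3K4me1 and 2.73 H3K27ac peaks per Mb, the densest in H3K27ac was 10p15.1 with 86 peaks at 30.7 per Mb. It was followed by 11q13.1 with 76 peaks at 30.4 per Mb and 10p11.22 with 91 peaks at 29.4 per Mb, where 36.9% of H3K4me1 peaks carried H3K27ac. Bands 12p13.1, 11q24.1, 10q25.2 and 7q31.2 came next at 27.5, 27.04, 26.3 and 25.4 per Mb. At the other end, 25 bands of 4 Mb or more had no listed H3K27ac peak. The largest H3K4me1 sets among these were in 14q12 (95 peaks), 8q21.13 (68), 4q31.3 (66), 11q25 (47) and 2p24.3 (42). Copy number in S2-VP10 cells was not analysed here and enters any count of peaks per Mb. Closely spaced peaks each count in these densities, which therefore do not count separate sites. Merging across 1 kb turned the 11206 H3K27ac peaks of the list into 6579. In 11q24.1, 45 of the 73 H3K27ac peaks lay in 1 cluster of 64.7 kb.

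The bands that hold ROR1 and several driver genes of pancreatic adenocarcinoma from the list fixed beforehand lay between 0.714 and 10.2 H3K27ac peaks per Mb. Each band contains many genes, and no peak was assigned to any of them. Band 1p31.3, which holds ROR1, the receptor tyrosine kinase-like protein used to sort the xenograft cells, had 207 H3K4me1 and 37 H3K27ac peaks. Its 4.87 H3K27ac peaks per Mb lay at percentile 68.4 of the bands, and 21 of its H3K4me1 peaks, 10.1% (6.73 to 15.0), carried H3K27ac. Band 9p21.3, home of the cell-cycle inhibitors CDKN2A and CDKN2B and of MTAP, stood highest of these driver bands. It had 10.2 H3K27ac peaks per Mb (58 peaks, percentile 90.2), with 23.5% (17.1 to 31.4) of 132 H3K4me1 peaks acetylated. Of the 58 peaks, 27 and 7 lay in 2 clusters of 48.2 and 20.1 kb. The density of this 5.7 Mb band thus rested largely on those clusters and does not describe the surroundings of any 1 gene. Band Xp11.3, home of the H3K27 demethylase KDM6A, had 6.25 per Mb and 24.1% (16.0 to 34.5), and 17q22, home of the WNT pathway ubiquitin ligase RNF43, had 5.14 per Mb and 20.5% (14.3 to 28.5). Band 3p24.1, home of the TGF-beta receptor TGFBR2, lay near the genome-wide share at 10.7%, with 4.44 per Mb.

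Lower in the ranking, 1p36.11, home of the chromatin remodeller ARID1A, was rich in H3K4me1 (164 peaks, 40 per Mb) but had 2.44 H3K27ac peaks per Mb and 4.27% (2.08 to 8.55) of its H3K4me1 peaks acetylated. Band 18q21.2, home of the TGF-beta signal transducer SMAD4, had 4 H3K27ac peaks (0.714 per Mb) and 4.88% (1.35 to 16.1) of its H3K4me1 peaks acetylated. Chosen after their values were seen, the MYC band 8q24.21 had 68 H3K27ac peaks (16.2 per Mb, percentile 96.7) with 18.5% (13.8 to 24.3) of its H3K4me1 peaks acetylated, and the band of the foregut regulator GATA6, 18q11.2, had 44 (7.33 per Mb, percentile 82.2) with 13.2% (9.42 to 18.2). The Wilson intervals of 9p21.3, Xp11.3, 17q22 and 8q24.21 lay above 11.3% and that of 1p36.11 below it, with no test between bands. These intervals treat neighbouring peaks as independent, and H3K27ac peaks were clustered, so they may be too narrow.

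H3K27ac peaks gathered in clusters. Joining them across gaps of up to 12 kb gave 4548 clusters, of which 2216 were single peaks, and the 557 with 5 or more peaks held 45.7% of all H3K27ac-covered bases. The most extensive cluster lay in 11q24.1 on chromosome 11 from 122008422 to 122073097, where 45 H3K27ac peaks covered 28.3 kb of a 64.7 kb span and H3K4me1 covered 84.1% of it. Next came a cluster in 9p21.3 on chromosome 9 from 21545956 to 21594109 (27 peaks, 26.2 kb covered), and one in 10p11.22 on chromosome 10 from 33225461 to 33275239 (22 peaks, 26.1 kb). The fourth lay in 1p31.1 on chromosome 1 from 84607082 to 84653533 (20 peaks, 21.5 kb). A pair of neighbours in 17q23.1 on chromosome 17, from 57825820 to 57884370 and from 57897589 to 57937278, covered 21.2 and 20.7 kb. The seventh, again in 9p21.3, from 21670148 to 21690213, had 7 H3K27ac peaks covering 18.5 kb and H3K4me1 over 98.6% of its span. Chromosomes 9, 10 and 12 each held 3 of the 20 most extensive clusters, which together held 6.21% of H3K27ac-covered bases, and H3K4me1 covered between 45.1% and 98.6% of each.

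Band 5p15.1 departed from this arrangement. On chromosome 5 from 16666722 to 16818367, 30 consecutive H3K27ac peaks had no overlapping H3K4me1 peak, where the next longest such run on any chromosome had 4, with runs broken at gaps over 100 kb. Fold enrichment in this run had a median of 9.56 (range 3.75 to 26.8), and the highest value anywhere else in the H3K27ac list was 18.4. The run held 14 of the 20 H3K27ac peaks with the smallest q-values. Its peaks were narrow, with a median of 311.5 bp (range 181 to 1004 bp). The 17 of them with fold enrichment of 8 or more had a median width of 329 bp, against 1137.5 bp (quartiles 766 and 1704) for the 988 such peaks elsewhere, of which 98.4% overlapped H3K4me1. Without the run, 91.5% of H3K27ac peaks overlapped H3K4me1. The list alone does not show whether the fold enrichment in the run measures acetylated chromatin, and the IgG library was not analysed here.

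**Figure D3:**
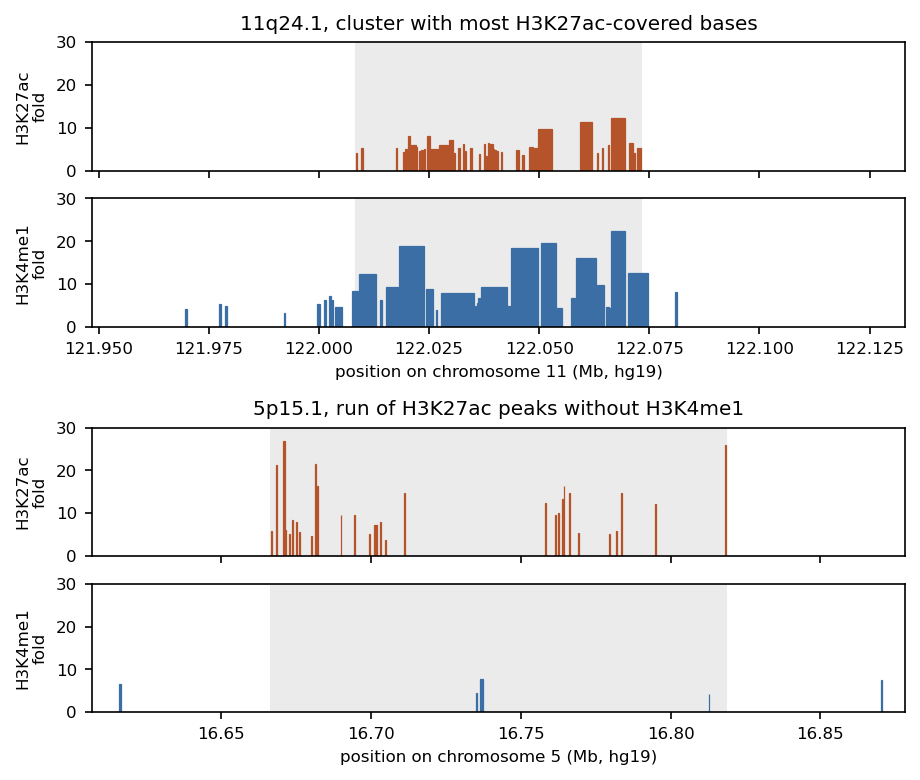
Peaks drawn to scale as bars at their hg19 position (horizontal axis, Mb) with the authors' fold enrichment as height (vertical axis) for H3K27ac (brown) and H3K4me1 (blue), at the 11q24.1 cluster (upper pair) and the 5p15.1 run (lower pair), each shaded grey. In 11q24.1 H3K4me1 peaks cover 84.1% of the span of the 45 H3K27ac peaks, and in 5p15.1 the 30 H3K27ac peaks reach a fold of 26.8 with no H3K4me1 peak under them.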

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

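The versions without the 5p15.1 run, without the strongest decile of H3K4me1 peaks, without peaks of the smallest width, and the fold-standardised chromosome 19 share were chosen only after the results were seen. The share of H3K27ac peaks on H3K4me1 stayed between 87.8% and 97.5% over 7 alternatives, 13.5 to 39.7 times its placement mean. The share of H3K4me1 peaks with H3K27ac stayed between 7.46% and 16.1% over 7 alternatives, 10.8 to 34.6 times its placement mean, the lowest share being that without the strongest decile. Placement within 1 Mb windows gave the lowest ratio for both. All of these had a permutation p of 0.002. With the higher-scoring 50% of both lists, the width ratio of H3K4me1 peaks with against without H3K27ac was 2.07 in place of 2.91, the fold ratio 1.42 in place of 1.76, and the width ratio for H3K27ac peaks 1.72 in place of 1.39; the cause was not tested. Joins of 5 and 20 kb gave 5176 and 4122 clusters, and 16 and 15 of the 20 most extensive met one of the 20 most extensive there. Without peaks of the smallest width, 56437 H3K4me1 and 10769 H3K27ac peaks remained. Standardised to H3K4me1 fold, the chromosome 19 share was 12.7% in place of 6.51%. Alternatives for promoter location, gene lists and the ROR1 gene were not run, since no hg19 annotation was used here. No paired analysis was possible because each group is 1 library. Depth is unknown, so a site without a listed peak cannot be read as unmarked.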

Other observations

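The width and copy-gain tests of the 5p15.1 run and the gene-density test of chromosome 19 were chosen only after the result was seen. No biological explanation was tested between groups of samples, since the peak lists come from 1 library of each mark.

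Bands of the palest stain carried 28.1 H3K4me1 peaks per Mb (24.7 to 31.5) and 5.44 H3K27ac peaks per Mb (4.19 to 6.85), with intervals that include the values of unstained bands. The next darker classes carried 21.4 and 4.07, then 15.5 and 2.66 peaks per Mb of H3K4me1 and H3K27ac. Centromeric bands held 186 H3K4me1 and 27 H3K27ac peaks, and variable heterochromatic bands held 37 and 2. Other bands dense in H3K27ac were 1p36.23 with 25 peaks per Mb, 9q22.32 with 24.4 and 1q42.3 with 24.2. Further extensive clusters lay in 10q25.2 (17.5 kb covered), 12p12.3 (17.2 kb), 15q22.33 (16.5 kb) and 4q13.3 (15.7 kb).

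The 5p15.1 run joins the strongest H3K27ac enrichment of the list to narrow peaks, none of which overlapped the 3 H3K4me1 peaks inside it. The run's peaks of fold 8 or more were 0.289 times as wide as such peaks elsewhere (0.265 to 0.319). The 16 peaks of that strength without H3K4me1 elsewhere had a median width of 683 bp. In width the run was thus unlike other strong H3K27ac peaks, but the test was chosen after this narrowness was seen. Its interval covers peaks of 1 locus in 1 library, so whether the run is an acetylated domain stays open. A local copy gain cannot be told apart from none. H3K4me1 density inside the run was 0.412 times that of the 500 kb on each side, with an interval of 0.0821 to 1.28 from 3 peaks against 48. The run was picked for H3K27ac peaks without H3K4me1, which itself favours a low density there, so this ratio cannot measure copy number. Short DNA fragments from 1 locus that entered the H3K27ac library alone, such as a spliced cDNA or a plasmid insert mapping to the exons of a gene, may be the source, in which case these folds would not measure H3K27ac, but this also stays open: width followed fold with a rho of 0.489 (0.156 to 0.712), near the 0.536 found elsewhere. The narrow, separated peaks prompted that hypothesis, and neither the exon positions of this locus nor the IgG library, which would bear on it, was analysed here.

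Chromosomes 19 and X had the lowest shares of H3K4me1 peaks with H3K27ac. Few genes cannot be the reason on chromosome 19, which has 24.5 protein-coding genes per Mb against a median of 5.64. That gene density was already known when the test was chosen, so it adds no evidence on the low share. Weaker H3K4me1 peaks could account for the low share on chromosome 19, where the median fold was 5.30 and the observed share was 1.12 times that expected at equal fold (0.709 to 1.59). For chromosome X the ratio was 0.785 (0.509 to 1.07), an interval that includes 1 but leaves room for a share well below the expected one. Why H3K4me1 peaks were weaker there was not tested, and copy number was not analysed here.

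The rise of the H3K27ac share with H3K4me1 enrichment was set against random placement. Placement gave 0.790% (0.379 to 1.17) in the strongest decile against the observed 46.3%. H3K27ac covered 0.190% of the chromosomes, so placement could hardly come near that share at these widths. Median H3K4me1 width rose with fold, from 337 bp in the weakest to 1893 bp in the strongest decile. No comparison at equal width was made, so how far width rather than enrichment carries the rise stays open. A detection limit of the H3K27ac list may lower the shares. With the strongest 25, 50, 75 and 100% of H3K27ac peaks, the share in the strongest H3K4me1 decile was 21.6, 32.5, 40.4 and 46.3%, and the weakest 25% of the list still added 5.96 points. The share was therefore still rising at the end of the list, though in shrinking steps of 10.97, 7.82 and 5.96 points. Adding peaks can only raise this share, so the rise does not by itself show a detection limit. How many of the remaining peaks a deeper library would find acetylated stays open.

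H3K27ac peaks without H3K4me1 often lay between H3K4me1 peaks, with H3K4me1 within 2 kb on both sides of 44.9% of them. A dip of H3K4me1 at the centre of acetylated sites is a hypothesis that this share cannot decide. It restates the pattern, and general closeness to H3K4me1 (a median distance of 513 bp) already lifts it above placement. Marked stretches that the peak caller split into separate H3K4me1 peaks stay open too, and H3K4me3 was not analysed here.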
